A study of Heliconius himera and Heliconius erato lativitta and Heliconius erato petiverana with 18 samples.

How the data were processed

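Messenger RNA was measured by RNA sequencing in whole wings of Heliconius butterflies at day 3 after pupation, from animals raised at about 27 °C, per the labels. The 18 libraries came from 3 taxa, Heliconius himera and the H. erato races lativitta and petiverana, with 3 numbered forewing (FW) and 3 numbered hindwing (HW) libraries in each, which makes 6 groups. RNA was selected for poly-A tails and made into libraries with a commercial NEB kit, per the labels' protocols. The labels do not say that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries.

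The deposited values were raw read counts per gene ID, 1 file per library, with no normalisation. TopHat, bedtools and DESeq2 are named in the submitters' processing notes, without versions or roles. The genome build, the annotation and the strand setting are not given in the sources used here. Each file listed 14612 gene IDs followed by 5 summary rows that carry the category names of a read counter. The summary rows, left out of library sizes and tests, held 49.4% to 62.4% of the reads. Reads outside any annotated feature made up 25.8% to 37.2%, reads aligned at more than 1 place 22.9% to 28.3% and reads overlapping more than 1 feature (ambiguous reads) 0.453% to 1.77%, while the remaining categories held 0 reads. All 3 taxa were counted against 1 list of IDs. A difference between taxa can therefore include differences in how well reads of a taxon align to the reference. Genes that overlap or have near-identical copies can lose reads to the ambiguous and multiply aligned categories, and are uncertain to that extent.

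The files pair the IDs with 0 gene names, and no reference annotation was used here. IDs are printed as deposited, their identities and positions were not analysed here, and the tests of preset gene lists planned before the data were examined were not run. The groups, the tests, the other settings to try and the rule for named IDs were fixed before the data were examined. With unnamed IDs the rule took, for HW against FW, the 2 highest and the 2 lowest IDs with adjusted p under 0.05, a mean of at least 1 CPM (counts per 1000000 gene reads) and the same sign in each taxon. For each pair of taxa it took 2 per direction, called with the same sign in both wings and ranked by the smaller of the 2 absolute log2 fold changes. For the interaction it took the 2 IDs with the smallest p. HEL_000265 was 1 of these 2. It was also called between wings, where it is named outside the rule and was chosen after its values were seen.

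Gene reads per library ranged from 4599197 to 17002996, and 10784 to 11965 IDs had at least 1 read. Counts were analysed in R 4.3.3 with edgeR 4.0.16. IDs were filtered with filterByExpr on the 6 groups, which kept 9957, and libraries were scaled by TMM factors. A quasi-likelihood model (glmQLFit, glmQLFTest) with 1 mean per group was fitted to all 18 libraries, with 12 residual degrees of freedom. The common dispersion was 0.361 and the prior degrees of freedom 1.95. Adjusted p is the Benjamini-Hochberg value over the 9957 IDs, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values are TMM-normalised unless called plain, and are given as mean ± SD. Ratios with a group that held 1 to 3 reads carry an exact 95% interval for counting error alone, and a ratio against a group with 0 reads is a bound at a floor of 3 reads over the group. No pair of libraries in a group agreed within sampling noise, with a chi-square of at least 16.8 per degree of freedom.

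The same steps were tested on simulated counts with 200 changed IDs among 9957. Libraries were drawn independently, with no number shared between wings. In the simulated test between wings 4.81% of unchanged IDs had an unadjusted edgeR p under 0.05, while 128 of all 9957 IDs did in the real one. The simulated shares therefore need not hold for the real libraries. For HW against FW over the taxa, 42% of 2-fold, 80% of 4-fold, 90% of 8-fold and 96% of 16-fold changes were recovered. For lativitta against petiverana in FW the shares were 4%, 48%, 72% and 76%, and for himera against lativitta in FW 8%, 54%, 64% and 70%.

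Whether equal numbers pair libraries was decided from deviations of log2 CPM (prior count 2) from the group means. FW and HW libraries with the same number correlated across IDs with r of 0.92, 0.87 and 0.85 in himera and 0.93, 0.85 and 0.87 in petiverana, so numbers pair the wings in these taxa. In lativitta the values were 0.60, -0.53 and -0.46, and equal numbers of different taxa gave -0.14 to 0.07, so numbers pair neither lativitta wings nor taxa.

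The other settings chosen before the data were examined were DESeq2 1.42.0, its median-of-ratios factors in edgeR, no filter, a filter at a mean count of 10, leaving out IDs unread in a taxon, fitting only the groups compared, a test against a 1.5-fold change, a replicate block, summing the FW and HW counts of a number, and leaving out each library in turn. Further settings were chosen after seeing the data. They left out the number 1 libraries of himera, of petiverana or of both, used the share of ambiguous reads (under or over 1%) as a term or compared taxa within such a set, and applied the replicate block to himera and petiverana alone. Principal components were computed from log2 CPM.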

Results

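Messenger RNA was profiled in whole forewings (FW) and hindwings (HW) of 3 Heliconius taxa, with 3 libraries for each taxon and wing. Heliconius himera and the lativitta and petiverana races of H. erato are Neotropical butterflies that differ in wing colour pattern. The wings were taken at day 3 after pupation. The series describes its aim only as examining mRNA abundance at this stage, and its design contrasts wings within a taxon and taxa within a wing. Libraries held 4599197 to 17002996 gene reads. The mean was 9444880 ± 3795239 in himera, 5923670 ± 1694071 in lativitta and 6867144 ± 1129972 in petiverana (SD, n = 6 libraries each).

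Libraries of the same taxon did not always resemble each other. The first principal component of log2 CPM held 59.1% of the variance and the second 14.9%. The first placed both himera number 1 libraries and all 6 petiverana libraries on 1 side, and himera numbers 2 and 3 with all 6 lativitta libraries on the other. The number 1 libraries of himera had Spearman correlations across IDs of 0.740 to 0.752 with other himera libraries and 0.846 to 0.877 with petiverana libraries. Libraries of a lativitta group correlated at 0.957 to 0.977. Petiverana number 1 correlated with numbers 2 and 3 of its wing at 0.798 to 0.822, against 0.949 and 0.953 between those. FW and HW libraries of a taxon and number correlated at 0.936 to 0.989. These correlations are across genes, which are not independent replicates.

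**Figure D1:**
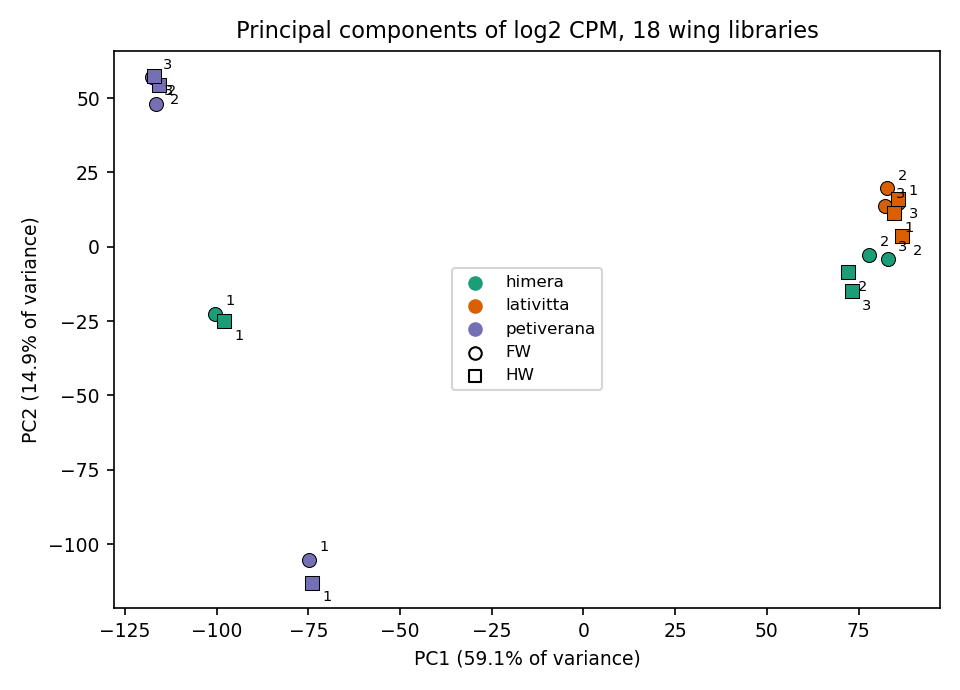
Scores of the 18 libraries on the first (x axis) and second (y axis) principal component of log2 CPM, with each component's percent of the variance on its axis. Each point is 1 library, coloured by taxon, shaped by wing and marked with its number; both himera number 1 libraries lie on the petiverana side of the first component, which holds 59.1% of the variance.

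The same sets of libraries differed in how reads were distributed. In the 8 libraries on the petiverana side, ambiguous reads made up 0.453% to 0.715% of reads and the 10 most abundant IDs took 30.7% to 33.7% of gene reads. In the other 10 libraries the ranges were 1.40% to 1.77% and 8.62% to 12.4%. All lativitta libraries were in the higher set for ambiguous reads and all petiverana libraries in the lower set. Only himera had libraries in both.

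The first comparison was between wings. HEL_004329 and HEL_004330 were read almost only in HW, in each taxon. HEL_004329 reached 17.3 ± 7.97 CPM in himera HW, 20.7 ± 1.69 in lativitta HW and 21.5 ± 2.36 in petiverana HW (SD, n = 3 each), from 537, 498 and 307 reads. The FW groups held 2, 3 and 2 reads of it. The HW to FW ratio was 198 in himera (95% interval 54.7 to 1643), 202 in lativitta (68.8 to 984) and 151 in petiverana (41.6 to 1256). HEL_004330 reached 8.04 ± 1.87, 9.72 ± 2.06 and 7.66 ± 2.16 CPM in HW of the same taxa (SD, n = 3 each), with 1 read in each FW group. Its ratios were 199 (35.4 to 7881), 290 (51.5 to 11499) and 110 (19.4 to 4402).

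**Figure D2:**
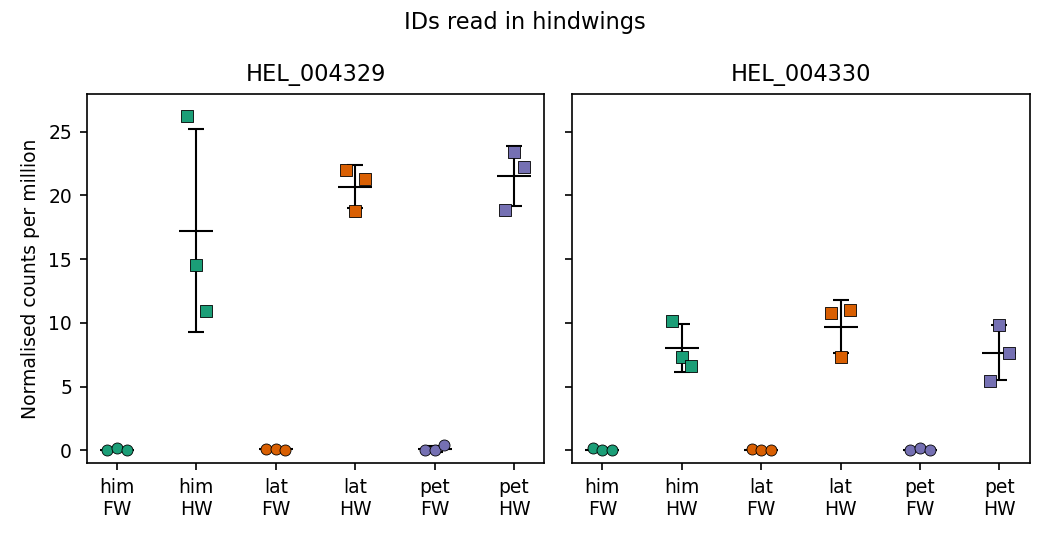
Normalised counts in CPM (y axis) of HEL_004329 and HEL_004330 in FW and HW libraries of himera (him), lativitta (lat) and petiverana (pet). Points are libraries, horizontal bars group means and vertical bars 1 SD (n = 3); every HW library lies above every FW library.

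Averaged over the taxa, HEL_004329 was higher in HW by 7.37 on the log2 scale (SE 0.46, edgeR adjusted p = 2.37e-06) and HEL_004330 by 7.10 (SE 0.47, adjusted p = 2.40e-06). HEL_001388 was lower in HW, with a log2 change of -2.57 (SE 0.41, adjusted p = 0.0498). It was at 4.30 ± 0.72 CPM in lativitta FW and 0.853 ± 0.877 in lativitta HW (SD, n = 3 each). HEL_000265 was also lower in HW, by -2.32 (SE 0.31, adjusted p = 0.0114), with -2.66 in himera, -4.44 in lativitta and 0.13 in petiverana. These 4 of 9957 IDs, 2 higher and 2 lower, passed the test over the taxa. In that fit 128 IDs had an unadjusted edgeR p under 0.05, against 684 with the replicate block within each taxon. Within himera it was 98 against 862, within petiverana 52 against 282 and within lativitta 68 against 511. Numbers do not pair the wings in lativitta, so the rise was not confined to taxa whose numbers do. Without a block, differences between numbers that both wings share stay in the spread of the fit. The wing tests are therefore strict, and the 4 IDs need not be all that differ between wings. The HEL_001388 call was lost in 14 of the 18 fits that each left out 1 library, with an adjusted p of 0.107 to 0.256. It was kept only without himera FW 3, himera HW 1, lativitta HW 2 or lativitta HW 3. It was also lost with median-of-ratios factors (adjusted p = 0.0507), without a filter (0.0726), against a 1.5-fold change (0.135) and with the replicate block within each taxon (0.0957). Leaving out the number 1 libraries of himera, of petiverana or of both gave an adjusted p of 0.096, 0.211 and 0.123. HEL_000265 did not pass without himera HW 2 (adjusted p = 0.0523), himera HW 3 (0.0539), lativitta HW 1 (0.060) or petiverana HW 2 (0.0503).

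Within himera, HEL_004329 and HEL_004330 alone passed, both higher in HW, with log2 changes of 7.56 (SE 0.81) and 7.17 (SE 0.81) and an edgeR adjusted p of 0.0021 each. Neither passed in the fit of the himera groups alone (adjusted p = 0.9999 each), where the count was 0 and 94 IDs had an unadjusted p under 0.05. With the replicate block fitted to all libraries the himera count stayed at 2. With the block fitted to himera and petiverana alone, where numbers pair the wings, it was 48, of which 27 were higher and 21 lower in HW. HEL_000265 in himera passed with that block (-2.75, adjusted p = 0.0226), with DESeq2 (adjusted p = 0.0058) and without the number 1 libraries of himera and petiverana (adjusted p = 0.0372). Within lativitta 3 IDs passed, HEL_004329 and HEL_004330 higher in HW and HEL_000265 lower (adjusted p = 0.0147). The HEL_000265 call was lost without any 1 of the lativitta libraries except FW 3, with adjusted p from 0.0514 without FW 1 to 0.215 without HW 3, and in the fit of the lativitta groups alone (0.199). Within petiverana HEL_004329 (adjusted p = 0.0055) and HEL_004330 (adjusted p = 0.0094) passed. Neither passed without petiverana FW 1, nor without petiverana FW 2, where the count was 0, and only HEL_004329 passed without petiverana FW 3. Neither passed in the fit of the petiverana groups alone (adjusted p = 0.508 each) or without both petiverana number 1 libraries (0.0989 each).

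Whether the wing difference depended on taxon was tested directly. In edgeR 0 IDs passed, 31 had an unadjusted p under 0.05, and DESeq2 called 1. The smallest unadjusted value of edgeR's test was that of HEL_000265 (adjusted p = 1). Its mean in HW was 1.03 ± 0.146 CPM in himera, 0.221 ± 0.106 in lativitta and 4.91 ± 2.24 in petiverana (SD, n = 3 each). HEL_007922 came next (adjusted p = 1), with 46.0 ± 58.3 CPM in himera HW and 2.0 ± 1.01 in himera FW (SD, n = 3 each), and 4 to 10 reads in each group of the other taxa. Neither difference held up against the spread between libraries after adjustment. With the replicate block within each taxon 446 IDs had an unadjusted edgeR p under 0.05 and 0 passed. The fit without a block keeps spread between numbers that both wings share. A count of 0 in it does not show that the wing difference is alike in the taxa.

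Himera was then compared with lativitta. HEL_009697 was at 88.1 ± 88.4 CPM in himera FW and 0.989 ± 0.600 in lativitta FW (SD, n = 3 each), a log2 difference of 6.42 (SE 0.98, edgeR adjusted p = 0.0113), and at 113 ± 86.7 and 1.02 ± 0.945 CPM in HW (6.73, SE 0.99, adjusted p = 0.0080). HEL_007008 was also higher in himera, by 6.70 in FW (SE 1.31, adjusted p = 0.037) and 5.16 in HW (SE 1.21, adjusted p = 0.047). HEL_007160 was at 7.12 ± 1.49 CPM in lativitta FW and 3.79 ± 1.81 in lativitta HW (SD, n = 3 each), with 4 and 3 reads in the himera groups. Its log2 differences were -5.45 (SE 0.81, adjusted p = 0.0113) and -5.44 (SE 0.84, adjusted p = 0.012). HEL_014346 was lower in himera by -4.17 (SE 0.87, adjusted p = 0.0416) in FW and -4.18 (SE 0.86, adjusted p = 0.0306) in HW. All 4 IDs lost the call in each wing when some single library was left out. HEL_009697 lost it without lativitta FW 1 (adjusted p = 0.0594), FW 2 (0.0772) or HW 3 (0.0674), and HEL_007160 without lativitta FW 2 (0.0552), himera HW 3 (0.0523), lativitta HW 1 (0.0542) or lativitta HW 3 (0.0674). HEL_007008 lost it in HW without any 1 of the 6 libraries compared (adjusted p 0.068 to 0.204), and in FW without himera 1 or 2 or lativitta 1 or 2 (0.0656 to 0.161). Among himera libraries number 1 held the most HEL_007008, at 341 CPM in FW against 70.1 and 27.4 in numbers 2 and 3, and without it the FW difference was 5.13 and the HW difference 4.08. HEL_014346 lost the call in FW without any 1 of the 6 libraries (adjusted p 0.0677 to 0.164), and in HW without himera 2 or 3 or lativitta 1 or 3 (0.0664 to 0.132).

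Between himera and lativitta, 93 IDs passed in FW, 47 higher in himera and 46 lower. In HW 189 passed, 94 higher and 95 lower. Leaving out any 1 library gave fewer. In FW 19, 17 and 62 passed without himera 1, 2 and 3, and 11, 3 and 37 without lativitta 1, 2 and 3. In HW it was 137, 59 and 25, then 6, 94 and 10. In both wings 33 were higher in himera and 30 lower, against 0.444 and 0.439 for independent lists, with 0 in opposite directions. FW and HW of a number may come from the same animal, so the wings are not independent samples. DESeq2 called 1112 IDs in FW, 707 higher and 405 lower in himera, and 1243 in HW, 780 higher and 463 lower. Within the higher set for ambiguous reads, which leaves 2 himera libraries per wing, 154 IDs passed in FW and 510 in HW. Fitting only the groups compared gave 0 in FW and 1 in HW, and summing the wings of a number gave 15.

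In the fit of all 18 libraries, himera and petiverana differed in more IDs than himera and lativitta. Within the sets for ambiguous reads these pairs keep unlike numbers of himera libraries, so their counts there cannot be ranked. The fits of only the groups compared gave too few calls to rank (0 against 1 in HW, 0 in both in FW). HEL_006341 was at 4.80 ± 0.171 CPM in himera FW and 4.34 ± 0.338 in himera HW (SD, n = 3 each), from 127 and 158 reads, and had 0 reads in petiverana. It was at least 22.0-fold higher in himera FW (edgeR adjusted p = 0.0382) and at least 20.5-fold higher in himera HW (adjusted p = 0.0356). HEL_009064 was higher in himera by 9.80 in FW (SE 2.46, adjusted p = 0.0325) and 9.48 in HW (SE 2.43, adjusted p = 0.0302) on the log2 scale. Himera numbers 2 and 3 carried this difference with 7844 to 11223 CPM, while himera number 1 had 8.86 CPM in FW and 11.6 in HW and the petiverana libraries 1.89 to 14.6. Within the lower set for ambiguous reads, which holds 1 himera library per wing, the HEL_009064 difference was 0.12 in FW (adjusted p = 0.972) and 0.63 in HW (adjusted p = 0.795). The other 3 IDs named for this pair lost the call there too but kept differences of similar size. In FW and HW these were 8.28 and 8.16 for HEL_006341, -10.87 and -12.97 for HEL_005333, and -11.89 and -10.60 for HEL_004024. The few or 0 reads on their lower side leave the size of these differences to the fit.

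Lower in himera than in petiverana were HEL_005333, by -11.98 in FW (SE 2.97, edgeR adjusted p = 0.0312) and -13.55 in HW (SE 3.14, adjusted p = 0.0217), and HEL_004024, by -11.57 (SE 2.95, adjusted p = 0.0339) and -12.32 (SE 3.05, adjusted p = 0.0269). Petiverana numbers 2 and 3 carried both. HEL_005333 was at 2043 to 3561 CPM in these 4 libraries and at 0.953 and 0.305 in petiverana number 1. HEL_004024 was at 467 to 2472 CPM in them and at 0.636 and 0 in number 1. None of the 4 IDs named for himera and petiverana passed in FW without himera FW 2 (adjusted p 0.0854 to 0.124) or FW 3 (0.0804 to 0.131), nor in HW without himera HW 2 (0.0805 to 0.113) or HW 3 (0.0739 to 0.104). HEL_009064 and HEL_006341 also failed without any 1 petiverana library of the wing compared, and HEL_005333 and HEL_004024 in FW without petiverana FW 2 (adjusted p 0.0680 and 0.0683) or FW 3 (0.0741 and 0.0825). In HW HEL_005333 failed without petiverana HW 3 (adjusted p = 0.0512), and HEL_004024 without HW 2 (0.0582) or HW 3 (0.0619).

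Between himera and petiverana, 727 IDs passed in FW, 418 higher in himera and 309 lower, and 915 in HW, 529 higher and 386 lower. Leaving out himera 1, 2 and 3 gave 1726, 119 and 166 in FW and 1853, 162 and 208 in HW, and leaving out petiverana 1, 2 and 3 gave 519, 172 and 228, then 853, 275 and 280. Which direction held more IDs depended on the libraries. Without petiverana FW 1 there were 221 higher and 298 lower in FW, and without petiverana HW 1 379 higher and 474 lower in HW. Without both, the counts were 606 and 672 in FW and 675 and 760 in HW. Without petiverana FW 2 they were 79 and 93, without HW 2 130 and 145, and without HW 3 135 and 145. Called in both wings with the same sign were 304 higher and 223 lower, against 22.2 and 12 for independent lists, and 0 were opposite. Since numbers pair the wings in both taxa, the lists are not independent and this excess tests nothing. Without both himera number 1 libraries 2897 IDs passed in FW, 1418 higher and 1479 lower, and 3068 in HW, 1496 higher and 1572 lower. Within the lower set for ambiguous reads, with 1 himera library per wing assumed to vary like the other groups, 383 passed in FW and 494 in HW. Fitting only the groups compared gave 0 in both wings, and DESeq2 called 1590 and 1760.

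In the fit of all 18 libraries, lativitta and petiverana differed in more IDs than the other pairs of taxa. With the set of ambiguous reads as a term, himera and petiverana differed in more IDs in HW (988 against 825) and fewer in FW (878 against 940). HEL_001189 was at 2692 ± 237 CPM in lativitta FW and 2919 ± 216 in lativitta HW (SD, n = 3 each), against 1.78 ± 1.10 and 3.6 ± 2.39 in petiverana. The log2 differences were 10.58 (SE 2.15, edgeR adjusted p = 0.0061) and 9.67 (SE 2.07, adjusted p = 0.0081). HEL_004364 was at 261 ± 37.5 and 223 ± 53.4 CPM in lativitta, with 6 reads in each petiverana group, and differed by 9.08 (SE 2.15, adjusted p = 0.0117) and 8.79 (SE 2.13, adjusted p = 0.0132). Himera libraries fell on both sides for these IDs. HEL_001189 was at 759 to 2797 CPM in himera numbers 2 and 3 and at 7.77 and 5.91 in himera number 1. With that term, the difference was 2.64 (adjusted p = 0.0579) and 1.72 (adjusted p = 0.199) for HEL_001189, and 1.13 (adjusted p = 0.619) and 0.87 (adjusted p = 0.721) for HEL_004364.

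HEL_008900 and HEL_011184 were lower in lativitta than in petiverana, and petiverana number 1 held most of their reads. HEL_008900 was at 6936 CPM in petiverana FW 1 and 7635 in HW 1, and at 5.95 to 163 in numbers 2 and 3. Its log2 differences were -13.93 (SE 3.59, edgeR adjusted p = 0.017) and -14.12 (SE 3.63, adjusted p = 0.0168), from 4 and 3 reads in lativitta. HEL_011184 was at 49859 and 62050.5 CPM in petiverana number 1 and at 1.63 to 12.05 in numbers 2 and 3, with differences of -13.81 (SE 4.63, adjusted p = 0.0448) and -14.08 (SE 4.67, adjusted p = 0.0428). In HW its groups overlapped, with lativitta HW 3 at 2.30 CPM and petiverana HW 2 at 1.63. Without petiverana FW 1 the HEL_011184 difference in FW was -2.62 (adjusted p = 0.487), and without petiverana HW 1 that in HW was -2.17 (adjusted p = 0.555). Without petiverana FW 2 the HEL_011184 difference in FW had an adjusted p of 0.0506. For HEL_008900 the difference in FW was -9.26 without petiverana FW 1 (adjusted p = 0.040), and that in HW was -7.36 without petiverana HW 1 (adjusted p = 0.0509). Without any 1 lativitta library of the wing compared, HEL_008900 had an adjusted p of 0.0594 to 0.0703 and HEL_011184 of 0.112 to 0.128. With the set of ambiguous reads as a term both lost the call in both wings, HEL_008900 at -9.78 (adjusted p = 0.113) and -9.98 (0.118), and HEL_011184 at -10.92 (adjusted p = 0.217) and -11.20 (0.220).

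Between lativitta and petiverana, 2386 IDs (24.0% of those tested) passed in FW, 1121 higher in lativitta and 1265 lower, and 2491 (25.02%) in HW, 1149 higher and 1342 lower. Without any 1 lativitta library the higher IDs exceeded the lower ones. Leaving out FW 1, 2 and 3 gave 536 higher and 381 lower, 583 and 382, and 725 and 545. Leaving out HW 1, 2 and 3 gave 527 and 354, 701 and 537, and 627 and 430. Without petiverana 2 and 3 in turn 1387 and 1370 passed in FW and 1419 and 1425 in HW. Called in both wings with the same sign were 874 higher and 1032 lower, against 129 and 170 for independent lists, and 0 were opposite. Numbers pair the wings in petiverana, so the lists are not independent and the excess tests nothing. These taxa lie in different sets for ambiguous reads, so no value within a set can be had for them. With the set as a term, which only himera libraries can estimate, 940 IDs passed in FW, 525 higher and 415 lower, and 825 in HW, 465 higher and 360 lower. Of these 369 and 320 were also called without the term in the same direction.

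**Figure D3:**
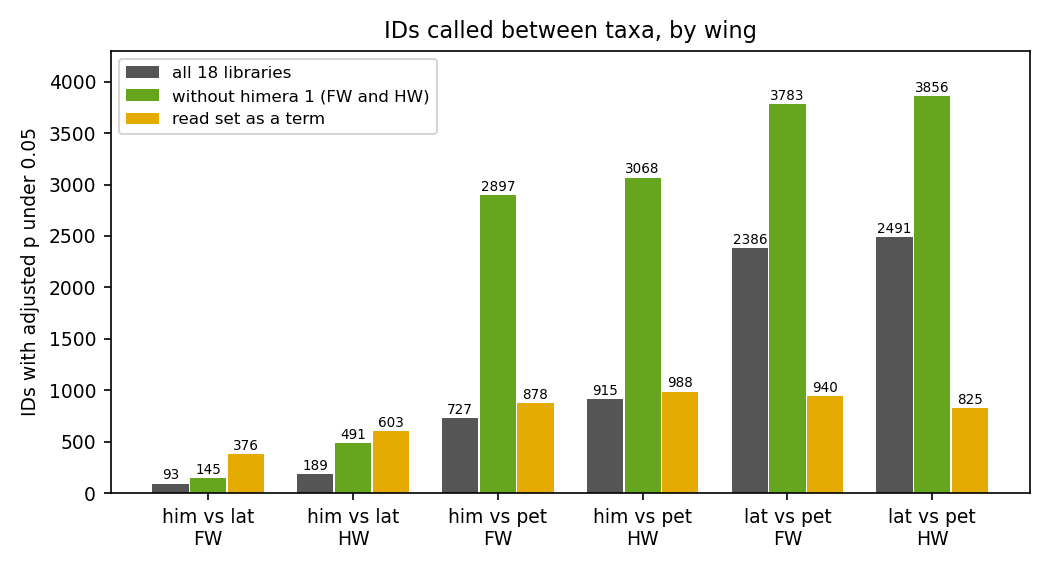
Number of IDs with an edgeR adjusted p under 0.05 (y axis) for each pair of taxa and wing (x axis; him himera, lat lativitta, pet petiverana). Bars show the fit of all 18 libraries, the fit without both himera number 1 libraries and the fit with the set of ambiguous reads as a term; for himera against petiverana in FW these gave 727, 2897 and 878.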

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

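The tests of other splits of the libraries, of a few abundant IDs and of developmental age were set before their results were seen. Those of another tissue, of ambiguous reads, of a preparation batch, of the library set, of abundant IDs in petiverana, of a wrong label and of exchanged numbers were chosen afterwards. Splits that part the number pairs over the taxa were added once the other splits had been seen.

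Reads outside the gene counts are given as values alone. Every library of this assay holds some, so exceeding a count of 0 is fixed and tests nothing. Their means over the 18 libraries were 29.1% for reads in no annotated feature, 1.14% for ambiguous reads and 24.8% for reads aligned at more than 1 place. Taking the mean of both wings per number, reads in no feature averaged 32.7 ± 2.26% in petiverana and 27.2 ± 1.20% in lativitta (SD, n = 3), with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 allows, and 0.225 after adjustment over 9 comparisons.

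Libraries of the same taxon lay far apart in himera and in petiverana, which ambiguous reads cannot carry as a whole, since at least 61.3% of gene reads sat on other IDs in himera number 1 than in numbers 2 and 3 of its wing, and at least 58.1% in petiverana number 1, while ambiguous shares differed by at most 1.05 points. Nor can a few abundant IDs. Without the 46 most abundant, at least 47.6% of the remaining reads in himera sat on other IDs in number 1 than in 2 and 3 of its wing. Between himera 2 and 3 it was 6.89% in FW and 8.63% in HW. In petiverana it was at least 42.5% for number 1, against at most 15.6% between 2 and 3. The first component without these IDs still separated the sets, himera number 1 from 2 and 3 among them, and held 58.2% of the variance. On a log scale so few IDs weigh little, so that component could hardly have changed. RNA from another tissue stays open. Plain CPM of HEL_004329 and HEL_004330 together in HW of the lower set was 0.554 of that in the higher set. That is above the 0.1 that dilution alone would need. Single libraries gave ratios down to 0.249, under the bound of 0.5 set for excluding it. A bound of 0.1 for the most distant libraries, tried once after these values were seen, would have excluded it and was not used. These ratios pool the taxa, so they cannot decide a difference within 1 taxon. In himera HW 1, 2 and 3 the IDs held 111 and 43, 315 and 159, and 111 and 67 reads. Gene reads there were 6838431, 17002996 and 8254547. In petiverana HW the reads were 62 and 18, 129 and 54, and 116 and 40, of 6289619, 7833916 and 7144161. Neither number 1 library was as low as 0.1 of the others, but each taxon gives only 1 such HW library. Developmental age and a library preparation batch both stay open. The age test correlated the main axis among libraries of 1 wing with himera numbers 2 and 3 minus lativitta in the other wing. Absolute correlations across IDs were 0.104 and 0.427 for the lativitta axes and 0.0926 and 0.105 for the petiverana axes. Himera number 1 did not enter this test, so it cannot decide whether age set that number apart. The labels give no batch, and petiverana number 1, in the same set as numbers 2 and 3, reached only 0.822 with them. A wrong label on himera number 1 stays open too, since only 1 ID set himera numbers 2 and 3 apart from all lativitta and petiverana libraries by over 10-fold, where the test required 10 in each direction, with 0% on the himera side in number 1. HEL_006341, at 4.88 and 4.49 CPM in number 1 and at 0 in petiverana, goes against a petiverana label as 1 ID alone. It was named by a test that counted number 1 as himera. In 146 IDs all himera libraries, number 1 included, lay on 1 side of all others, 78 above and 68 below. That count does not settle the label, since 6 of the 84 choices of 3 taxon and number pairs gave as many. A wrong label on petiverana number 1 was not tested. Its highest correlation with numbers 2 and 3 of its wing was 0.822, while himera number 1 reached 0.877 with petiverana libraries.

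Lativitta and petiverana differed in 24.0% of tested IDs in FW. With the set of ambiguous reads as a term 940 IDs passed in FW, between the bounds set for and against the set as the cause, and only himera libraries inform that term. The library set and the taxa cannot be told apart here, because lativitta and petiverana each lie wholly in 1 set and himera, the only taxon in both, has 1 number in the lower. A difference between the races, which the design names, stays open.

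In lativitta, FW 2 correlated with HW 3 (r = 0.73) and FW 3 with HW 2 (r = 0.63), across IDs. Numbers exchanged in 1 wing are a candidate explanation. The mean correlation was 0.652 for the exchanged matching and -0.132 for the labelled one, while the labelled matching was highest in himera (0.879) and petiverana (0.883). With 6 possible matchings, 1 is highest by chance, which keeps this open, and the labels were used as given. No biological explanation was tested.

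Over the taxa, 2 of 100 splits of the 18 libraries, the real one included, gave as many IDs as the 4 called between wings, with 309 as the highest other, which points to a structure of the samples, and these splits ignore that numbers pair the wings in himera and petiverana. Of 100 splits that part all those pairs, 1 gave as many as 4, the real one, with 0 as the highest other. This argues against chance for the count as a whole. Since the others gave 0, HEL_004329 and HEL_004330 alone would have given the same result. It therefore does not bear on HEL_001388 or HEL_000265 singly. Within himera 5 of 10 splits gave at least the real 2, the highest being 910 for a split that kept both number 1 libraries together. Within petiverana 2 of 10 gave at least the real 2, the highest being 175, again with both number 1 libraries together. Of the 4 splits that part all number pairs, the 3 others gave 0 in each of these taxa. Within lativitta 1 of 10 splits gave as many as the real 3, with 0 as the highest other. For each pair of taxa in each wing 1 of 10 splits gave as many as the real 93 and 189 (himera and lativitta), 727 and 915 (himera and petiverana) and 2386 and 2491 (lativitta and petiverana), with 0 as the highest other. With 10 splits no share under 0.05 can be reached. For the interaction all 100 of 100 splits gave at least the real 0, which is fixed in advance and tests nothing. The highest other gave 461, and which libraries that split put together was not examined.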

How the results depend on the processing

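Leaving out number 1 libraries, the ambiguous-read set, and the block on himera and petiverana alone were chosen after the data were seen; the rest was planned. No called log2 change of a named ID reversed; HEL_000265 in petiverana, not called, ranged from -0.26 to 0.40 and was below 0 without petiverana FW 3 or HW 1. Where no construction is named, the cause was not tested. Tests of gene lists were not run, since the files pair the IDs with 0 names. Counts follow the order himera-lativitta FW, HW, himera-petiverana FW, HW, lativitta-petiverana FW, HW. For named IDs, 451 planned values kept their side of the threshold, 162 fell short of it and 1 passed newly; of the added values 149, 33 and 2 did so.

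DESeq2 called 9 between wings over the taxa, 6 in himera, 17 in lativitta, 1112, 1243, 1590 and 1760 for himera against the others and 1 for the interaction. Without a filter, with 13620 IDs tested, himera-lativitta gave 38 and 97. Fitting only the groups compared, with fewer libraries to estimate the spread, gave 0 between wings in himera and in petiverana, and 0, 1, 0 and 0 for himera against the others. With as few libraries it gave 2 between wings in lativitta, and 2363 and 2247 in lativitta-petiverana. Fewer libraries alone therefore do not account for the fall in himera. The calls for himera against the others depended on a spread estimated over all 6 groups together. A test against a 1.5-fold change, a stricter question, gave 5, 20, 125, 163, 1032 and 975. Summing the wings of a number, with fewer samples, gave 15 in himera-lativitta and 371 in himera-petiverana.

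The replicate block within each taxon gave 3 over the taxa, 2 in himera, 3 in lativitta, 3 in petiverana and 0 for the interaction. Fitted to himera and petiverana alone it gave 48 in himera. Over all groups, where samples share only a number, the block gave 167, 353, 945, 1121, 2810 and 2981. Within lativitta only number 1 correlated best with its own number.

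Without both himera number 1 libraries the counts were 145, 491, 2897, 3068, 3783 and 3856. Without those of petiverana they were 385, 551, 1278 and 1435 for himera against the others, and 0 between wings in petiverana. Without all 4 they were 1105, 1554, 4202, 4293, 4589 and 4673, with 12 between wings in himera and 1 for the interaction. With the ambiguous-read set as a term the counts were 376, 603, 878, 988, 940 and 825. Within the higher set himera-lativitta gave 154 and 510, and within the lower set himera-petiverana gave 383 and 494.

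Leaving out each library in turn gave 2 to 5 between wings over the taxa (2 without himera HW 2, himera HW 3, lativitta HW 1 or petiverana HW 2), 2 to 4 in himera (4 without HW 1), 2 to 3 in lativitta, 0 to 2 in petiverana (0 without FW 1 or FW 2, 1 without FW 3) and 0 to 0 for the interaction. For himera-lativitta FW the range was 3 to 62: without himera 1, 2 and 3 it was 19, 17 and 62, without lativitta 1, 2 and 3 it was 11, 3 and 37. In HW it was 6 to 137: 137, 59 and 25, then 6, 94 and 10. For himera-petiverana FW it was 119 to 1726: 1726, 119 and 166 without himera, 519, 172 and 228 without petiverana. In HW it was 162 to 1853: 1853, 162 and 208, then 853, 275 and 280. For lativitta-petiverana FW it was 917 to 1992: 917, 965 and 1270 without lativitta, 1992, 1387 and 1370 without petiverana. In HW it was 881 to 2155: 881, 1238 and 1057, then 2155, 1419 and 1425. Simulated 2-fold changes were recovered at 42% between wings and 4% for lativitta-petiverana FW. The simulated libraries were independent, unlike the paired wings of himera and petiverana, so the real tests can differ from these shares.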

Other observations

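The tests in this part were set before their results were seen, except the counts within a wing, which were chosen afterwards.

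IDs called between lativitta and petiverana in both wings often carried consecutive numbers. Among 1906 such IDs, 368 consecutive pairs were called in the same direction, against a mean of 146 and a maximum of 194 in 10000 random placements (permutation p = 0.0001, the smallest they can give). Among the 200 IDs with the largest spread of log2 CPM there were 39 consecutive pairs, against a mean of 3.16 and a maximum of 12 (permutation p = 0.0001, the smallest they can give). Both counts argue against a random placement along the ID order. Whether consecutive IDs are neighbours in the genome was not analysed here, and reads shared between similar neighbouring genes stay open.

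In 719 IDs all 6 petiverana libraries lay on 1 side of all other libraries, 350 above and 369 below. Of the 84 ways to choose 3 of the 9 taxon and number pairs, 2 gave as many, the real one included. Numbers do not pair the wings in lativitta, so these choices exclude nothing. Within a wing, where no pairing is needed, petiverana gave 1466 such IDs in FW and 1455 in HW. Of the 84 choices of 3 of the 9 libraries, 3 gave as many in each wing. This argues only against a choice made at random among all 9 libraries. Petiverana lies wholly in the lower set for ambiguous reads, as does the choice that gave the most, so its rank does not separate taxon from set. Lativitta gave 1553 and 1617, reached by 2 of the 84 choices in each wing, and himera 479 and 527, reached by 9 and 7, so for himera a chance choice stays open. Over both wings, the choice with more than petiverana, 935 IDs, was himera number 1 with petiverana numbers 2 and 3, which is no group of the study. The libraries with these numbers also gave the most within each wing, with 1656 and 1644, which points to a structure of the samples. Lativitta gave 683 such IDs over both wings, reached by 3 of the choices, and himera 146, reached by 6.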
